A study of Danio rerio with 6 samples.

How the data were processed

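The samples were 3 pools of wild-type control and 3 pools of mcm5 mutant zebrafish, whole animals at 3.5 days post-fertilisation. Per the labels' protocols, poly(A) RNA was fragmented, reverse transcribed, tagged with molecular identifiers (UMIs), amplified by PCR and sequenced, and adapters were removed. HISAT2 is named in the submitters' processing notes, with no version. The counter, the use of strand, the collapse of UMIs, the genome build and the annotation are not given in the sources used here. Without a known strand, reads of overlapping or antisense genes cannot be told apart, and reads of near-identical copies may be split between them. The totals were between 9839226 and 12619270 counts per sample. The deposited table holds raw counts per gene, as whole numbers whose totals differ between samples, and the authors' counts were used without change. Of its 37655 features, 32520 carry an Ensembl gene ID and 5135 an ID of the authors' own with no Ensembl gene, whose origin is not given. Symbols came from a table of gene names, which matched 29201 IDs, and 6314 of these share their symbol with another ID and are then given with the ID. All columns of the table were mapped to a sample by their names. No genome positions are given, since the build is not known.

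Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr at its defaults (a minimum count of 10 and a minimum total of 15), which left 23366 genes, and libraries were scaled with TMM factors between 0.959 and 1.12. Mutants were compared with controls by the quasi-likelihood F-test with no covariate, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The standard error of a log2 fold change was taken from its F statistic. CPM are TMM-scaled, and values are mean ± SD over 3 samples. The common biological coefficient of variation was 18.5%. Replicates of a group differed by more than counting noise in a chi-square comparison of their counts (between 4.05 and 21.8 per degree of freedom), so no library was counted as a duplicate. Intervals and lower limits of detection (3 counts per library) cover counting error only, since it is not given whether reads of 1 molecule were collapsed.

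The test, the filter, 18 gene lists (799 members, of which 711 matched a gene), the rule for named genes and the alternatives were chosen before the data were examined. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 18 lists, and their members were counted past the threshold over all genes and adjusted over the list alone. The lists were written from general knowledge of zebrafish genes, and a gene in 2 lists counts in both. The genes named were mcm5, stat1a, stat1b, bcl2a and tp53, the 2 members of each list with the smallest p past the threshold (or, where none passed, the member with the highest mean CPM), and the 5 largest rises and falls among genes past the threshold with a mean of at least 5 CPM, no overlap of the groups and a symbol that is not a clone name. Other genes named were chosen after their values were seen.

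The alternatives were DESeq2 size factors, library size alone, no filter, a filter of at least 1 CPM in at least 3 samples, the Wald test of DESeq2 1.42.0, limma-voom, the replicate number as a block, each sample left out in turn, an inter-gene correlation estimated from the data, and fry. Alternatives added after seeing the data left out the features without an Ensembl gene, mcm5 from the MCM helicase list, and the p53 members from the Bcl-2 and caspase lists. The same steps were tested on simulated data for the comparison of mcm5 mutants with controls, made from the real means, library sizes and dispersions with 200 changed genes (50 per fold size). The changed genes were drawn from those with a mean of at least 1 CPM. Of 23084 genes run, edgeR recovered 3 of 50 genes changed 1.5-fold and 22 of 50 changed 2-fold. It recovered 39 of 50 changed 4-fold and 46 of 50 changed 8-fold, and called 8 unchanged genes. DESeq2 recovered 9, 26, 40 and 46 of 50 at these fold sizes and called 27 unchanged genes, and limma-voom called 6. In a further simulation over 23048 genes, with 1 list moved 1.3-fold, camera called that list and none of the other 17. Each gene was drawn independently, so this does not show how often camera calls lists whose members vary together. In the real data the estimated correlation was 0.61 for the exocrine pancreas list and 0.52 for the photoreceptor and lens list. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.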

Results

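Poly(A) RNA was sequenced from whole zebrafish at 3.5 days post-fertilisation, in 3 samples of wild-type controls and 3 samples of mcm5 mutants. The series asks which transcripts change downstream of mcm5, a subunit of the MCM helicase that opens DNA for replication, and its title points to Stat1, bcl2, apoptosis and immature T lymphocytes. Each sample was a pool, since about 150 fish per genotype were divided among the 3 replicates, so p-values measure the spread among these pools. The count table held between 9839226 and 12619270 counts per sample, and between 28772 and 29059 of its 37655 features had at least 1 count in a given sample. Control replicate 1 stood apart from the other controls. Its log2 CPM correlated with theirs across genes at r = 0.952 and r = 0.956, against r = 0.977 between control replicates 2 and 3.

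The transcript of mcm5 (ENSDARG00000019507) was 6.95-fold lower in the mutants. The 3 control samples held 641, 711 and 749 counts and the 3 mutant samples 83, 123 and 93, or 62.7 ± 6.32 CPM against 9.0 ± 1.01 CPM (SD, n = 3 each), so the level in every library matched its label. The log2 fold change was -2.80 (SE 0.13, adjusted p = 0.000308 in edgeR's quasi-likelihood test). Of the 9 measured genes of the MCM helicase list, mcm5 was the only one past the threshold over all genes, and 4 were lower when adjusted over the list alone. All 9 had a negative log2 fold change, with a median of -0.25, and the list was lower as a set (camera, adjusted p = 4.03e-07), also with mcm5 itself taken out (adjusted p = 0.0243, chosen after the data were seen).

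Genes of DNA synthesis and mitosis were also lower. Of the 43 measured mitosis and G2/M genes, 7 fell, with log2 fold changes between -1.03 and -0.52, and none rose, with 18 lower when adjusted over the list alone. The proliferation marker mki67 went from 150 ± 11.2 to 85.9 ± 2.59 CPM (SD, n = 3 each, log2 fold change -0.81, SE 0.09, adjusted p = 0.00305), and the centromere protein gene cenpf from 43.0 ± 1.33 to 21.1 ± 3.01 CPM (log2 fold change -1.03, SE 0.12, adjusted p = 0.00418). The mitosis list had a median log2 fold change of -0.35 and was lower as a set (adjusted p = 6.15e-09). Among 48 DNA replication genes, 2 fell over all genes and 2 were lower when adjusted over the list alone. DESeq2 called 4 lower. The 2 in edgeR were rrm1, the large subunit of ribonucleotide reductase (log2 fold change -0.59, adjusted p = 0.00593), and slbp, the histone stem-loop binding protein (log2 fold change -0.60, adjusted p = 0.0241). The replication list had a median of -0.23 and an adjusted p of 6.15e-05, which became adjusted p = 0.0791 with an estimated correlation. With 1 sample left out, the number of mitosis genes past the threshold was 3 without control replicate 3, mutant replicate 1 or mutant replicate 3, 4 without mutant replicate 2 and at most 9. The slbp call was kept only without control replicate 1, and the other adjusted p-values were between 0.0526 (without control replicate 2) and 0.113 (without mutant replicate 2). The rrm1 call ended without mutant replicate 1 (adjusted p = 0.0553).

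**Figure D1:**
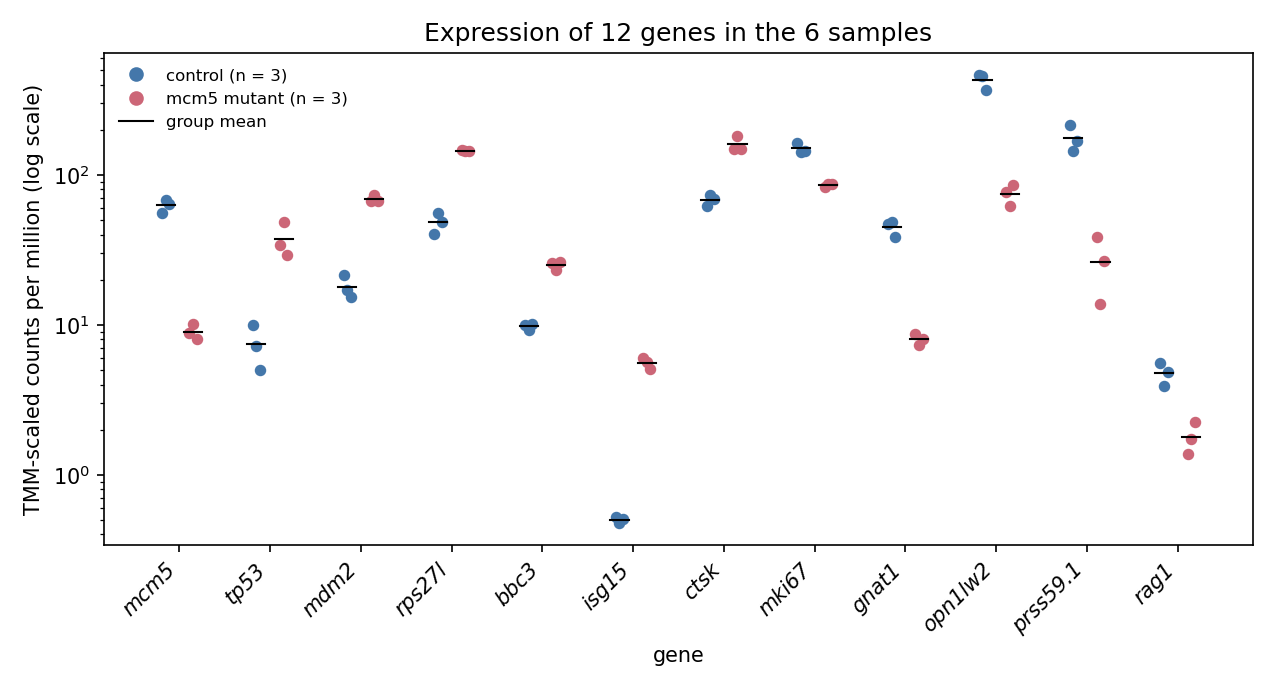
TMM-scaled CPM (log axis) of 12 genes in each of the 6 samples, with the 3 controls in blue, the 3 mcm5 mutants in red and a black line at each group mean. The groups do not overlap for any of these genes, with mcm5 at 62.7 against 9.0 CPM and mdm2 at 18 against 69.2 CPM on average.

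Over the whole transcriptome, 910 of 23366 tested genes differed between mutants and controls at a false discovery rate of 0.05, 347 of them higher and 563 lower in the mutants. At least a 2-fold change was found for 579 of them, 141 higher and 438 lower. The largest rises among named genes of at least 5 CPM with no overlap between the groups were of jac8 (14.1-fold), of bmb, the nuclear envelope gene brambleberry (9.95-fold), of sspo, which encodes the SCO-spondin of the Reissner fibre (7.35-fold), of the chemokine gene cxcl18b (7.15-fold) and of tp53 (5.03-fold). The largest falls were of the cone transcription factor gene six7 (14.1-fold), of rgs9 (ENSDARG00000037925), a regulator of phototransduction (12.7-fold), of the pancreatic elastase gene ela2 (11.8-fold), of the photoreceptor gene rp1l1b (10.7-fold) and of the GABA receptor subunit gene gabra6 (ENSDARG00000075058, 10.2-fold). Their adjusted p-values lay between 0.000704 and 0.0173. The call for sspo ended without control replicate 3, mutant replicate 1 or mutant replicate 2 (adjusted p = 0.0551, 0.0748 and 0.0738). All 910 genes had no overlap between the groups, as had 26.8% of all tested genes, where chance gives 10%. Leaving out control replicate 3 gave 481 genes, and leaving out mutant replicates 1, 2 and 3 gave 345, 331 and 459. DESeq2 called 1423 genes. Scaling by library size alone gave 210 higher and 599 lower genes, and it moved the median log2 fold change of all genes from -0.01 to -0.12.

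Genes of the p53 response, tp53 among them, were higher in the mutants. Of 33 measured members 11 rose, with log2 fold changes between 0.49 and 2.33, none fell and 22 did not pass, with 13 higher when adjusted over the list alone. Of all 33 members, 7 had a negative log2 fold change. The transcript of tp53 itself went from 7.42 ± 2.51 to 37.3 ± 10.2 CPM (SD, n = 3 each, log2 fold change 2.33, SE 0.28, adjusted p = 0.00435). That of mdm2, the ubiquitin ligase of p53, went from 18 ± 3.11 to 69.2 ± 3.71 CPM (log2 fold change 1.94, SE 0.13, adjusted p = 0.000677). The p53 target rps27l went from 48.3 ± 7.77 to 145 ± 2.24 CPM (log2 fold change 1.59, SE 0.12, adjusted p = 0.000942). The list median was 0.37 and the list was higher as a set (adjusted p = 3.77e-17, adjusted p = 0.0374 with an estimated correlation). With any 1 sample left out, 9 to 12 of its members were called. None of the 49 measured genes of DNA damage signalling and repair passed in edgeR, over all genes or adjusted over the list alone, nor in DESeq2 or limma-voom, and 7 had an unadjusted p under 0.05. Its most abundant member parp1 stood at 55.6 ± 6.71 CPM in controls and 44.7 ± 1.26 CPM in mutants (log2 fold change -0.31, adjusted p = 0.145). The median of this list was -0.16 and its set test gave an adjusted p of 0.0575, which passed without mutant replicate 2 (adjusted p = 0.0380), with no filter (0.0335) and with limma-voom (0.00924).

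Of 23 Bcl-2 family genes 2 rose, none fell and 21 did not pass, with 6 higher when adjusted over the list alone. DESeq2 called 4 higher and limma-voom 1. The 2 that rose in edgeR were bbc3, the BH3-only gene also named Puma (9.77 ± 0.475 to 25.1 ± 1.77 CPM, SD, n = 3 each, log2 fold change 1.36, SE 0.12, adjusted p = 0.00122), and the pore-forming effector gene bax (log2 fold change 0.49, SE 0.11, adjusted p = 0.0489), both also members of the p53 list. The bax call was kept only without control replicate 2 among the fits with 1 sample less, with an adjusted p of up to 0.184 (without mutant replicate 2). It also ended with library size alone (adjusted p = 0.0698), no filter (0.0508) and limma-voom (0.0550). The Bcl-2 list was higher as a set (median 0.13, adjusted p = 0.00381), and this call ended with an adjusted p = 0.368 with an estimated correlation, with an adjusted p = 0.0939 without control replicate 1, and with an adjusted p = 0.144 for the 20 members outside the p53 list, the last chosen after the data were seen. In control replicate 1 the members of the Bcl-2 list lay a median of 0.24 below the other controls on the log2 scale. Of 26 caspase and apoptosis execution genes 4 rose and none fell, with 6 higher when adjusted over the list alone. The initiator caspase gene casp8 rose from 10.6 ± 0.817 to 22.5 ± 1.13 CPM (log2 fold change 1.08, SE 0.12, adjusted p = 0.00288), and the cytokine gene tnfb rose from a low level (log2 fold change 1.75, SE 0.30, adjusted p = 0.0202), a call that ended without mutant replicate 1 or 2 (adjusted p = 0.0908 and 0.0825). The list median was 0.25 and the adjusted p as a set 1.66e-05. With 1 sample left out, 1 of these genes was called without mutant replicate 2, 2 without control replicate 2, control replicate 3 or mutant replicate 1, and at most 4. The set call held for the 24 members outside the p53 list (adjusted p = 0.000177, chosen after the data were seen).

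For the genes of the series title, bcl2a (ENSDARG00000094704) stood at 9.24 ± 1.2 CPM in controls and 10.4 ± 1.97 CPM in mutants (SD, n = 3 each, log2 fold change 0.17, SE 0.18, adjusted p = 0.653). The other bcl2 gene (ENSDARG00000089109), named here after its values were seen, had a log2 fold change of -0.35 (SE 0.15, unadjusted p = 0.0437, adjusted p = 0.2315). Both genes that carry the symbol stat1 were measured, and the sources used here do not say which is stat1a and which is stat1b. One of them (ENSDARG00000006266) stood at 56.8 ± 4.14 CPM in controls and 60.1 ± 1.3 CPM in mutants (log2 fold change 0.08, SE 0.09, adjusted p = 0.659). The other (ENSDARG00000076182) had too few counts to pass the filter of the main fit, with 0, 0 and 1 counts in the control samples and 8, 9 and 11 in the mutant samples. This is a ratio of 26.3 per sequenced count (95% exact interval 4.35 to 1076, which covers counting error only). These bcl2 and stat1 values are levels in whole fish and do not show the levels in immature T lymphocytes. Of 68 matched genes of the Stat1 and interferon list, 32 did not pass the filter. Of the 36 measured, 5 rose and none fell, with 8 higher when adjusted over the list alone and a median of 0.26. The ubiquitin-like isg15 rose from 0.505 ± 0.022 to 5.59 ± 0.504 CPM (log2 fold change 3.44, SE 0.25, adjusted p = 0.000898), and socs3 (ENSDARG00000026611), a feedback inhibitor of JAK-STAT signalling, from 28.9 ± 4.67 to 76.6 ± 8.52 CPM (log2 fold change 1.41, SE 0.14, adjusted p = 0.00210). For isg15 the controls held 6, 5 and 6 counts, under the minimum of 10, and the mutants 57, 69 and 58. The list was higher as a set (adjusted p = 2.46e-08).

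Genes of neutrophils and macrophages were higher in the mutants, and the recombinase gene rag1 of immature lymphocytes was lower. Of 48 matched thymus and T lymphocyte genes only 26 had enough counts for the test, and 3 (lck, cd8a and il15ra) had no count in any library, which allows up to 0.305 CPM in the shallowest one if the gene models used for counting, which are not given, cover their transcripts. The transcript of rag1 fell, with 64, 41 and 57 counts in controls and 13, 21 and 26 in mutants, or 4.79 ± 0.821 against 1.79 ± 0.446 CPM (SD, n = 3 each, log2 fold change -1.41, SE 0.26, adjusted p = 0.0283). Of the fits that left out 1 sample, only that without control replicate 2 kept this call (adjusted p = 0.0413), and the others gave between 0.0514 (without mutant replicate 3) and 0.120 (without mutant replicate 2). Adjusted over the list alone, 1 gene was higher and 1 lower. DESeq2 called 1 higher and 2 lower over all genes. The list did not differ as a set (median -0.03, mean 0.01, adjusted p = 0.821, direction up). Of 22 neutrophil and macrophage genes 8 rose and none fell, with 17 higher when adjusted over the list alone. The cathepsin genes ctsk (68.2 ± 5.37 to 160 ± 19.5 CPM, log2 fold change 1.23, SE 0.11, adjusted p = 0.00161) and ctss2.1 (12 ± 2.05 to 29.3 ± 0.476 CPM, log2 fold change 1.29, SE 0.14, adjusted p = 0.00288) were among them. This list had a median of 0.67 and was higher as a set (adjusted p = 2.62e-15, adjusted p = 0.0439 with an estimated correlation). In control replicate 1 its members lay a median of 0.30 below the other controls on the log2 scale. Without that sample 7 genes were called, and 4 without control replicate 3, mutant replicate 1 or mutant replicate 2, 5 without mutant replicate 3 and 6 without control replicate 2. Of 17 stem and progenitor genes of blood, 1 rose, the myeloid transcription factor gene spi1 (log2 fold change 0.91, adjusted p = 0.0208), and 1 fell, the chromatin protein gene hmga1a (log2 fold change -0.49, adjusted p = 0.0358), with the same numbers adjusted over the list alone. Both calls ended without control replicate 3 or any 1 mutant sample, with adjusted p-values of up to 0.10 for spi1 and up to 0.188 for hmga1a, each without mutant replicate 1. This list did not differ as a set (median 0.05, and -0.05 with scaling by library size alone, adjusted p = 0.574). Among 19 erythroid genes none passed in edgeR, over all genes or adjusted over the list alone, nor in DESeq2 or limma-voom, and 2 had an unadjusted p under 0.05. The globin gene hbae3 stood at 811 ± 244 CPM in controls and 867 ± 203 CPM in mutants, and the erythroid list at a median of -0.10 (adjusted p = 0.430). Among the fits with 1 sample less, the set test of this list passed only without control replicate 1 (adjusted p = 0.0313). In that sample its members lay a median of 0.43 below the other controls on the log2 scale.

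Photoreceptor genes fell, and their list had the lowest median of the 18 lists. Of 41 measured photoreceptor and lens genes 25 fell, with log2 fold changes between -3.38 and -1.31, and none rose, with 32 lower when adjusted over the list alone. All 25 belonged to photoreceptors, of which 28 genes were measured, a split made after the data were seen. None of the 13 measured lens genes passed in edgeR or limma-voom, while DESeq2 called 2 lower, and 6 had an unadjusted p under 0.05. The rod transducin gene gnat1 went from 44.7 ± 5.54 to 8.03 ± 0.661 CPM (SD, n = 3 each, log2 fold change -2.48, SE 0.13, adjusted p = 0.000445), and the red cone opsin gene opn1lw2 from 430 ± 54.3 to 74.7 ± 11.8 CPM (log2 fold change -2.52, SE 0.15, adjusted p = 0.000610). The counting could split reads between opn1lw2 and its near-identical neighbour opn1lw1, so the level of opn1lw2 is uncertain. The list median was -2.28 and the list was lower as a set (adjusted p = 1.53e-80, adjusted p = 0.0374 with an estimated correlation). Control replicate 1 lay a median of 0.43 above the other controls on the log2 scale over this list, and without it 25 genes were called. Of 38 neural and retinal progenitor genes 13 fell and none rose, with 27 lower and 1 higher when adjusted over the list alone. They included the transcription factor genes insm1 (ENSDARG00000091756, 22.8 ± 2.85 to 8.66 ± 1.23 CPM, log2 fold change -1.40, SE 0.15, adjusted p = 0.00305) and neurod4 (5.03 ± 1.81 to 0.483 ± 0.191 CPM, log2 fold change -3.35, SE 0.41, adjusted p = 0.00480). This list had a median of -0.64 and was lower as a set (adjusted p = 2.56e-19, adjusted p = 0.0353 with an estimated correlation). With 1 sample left out, 6 of its genes were called without mutant replicate 1 and 7 without mutant replicate 2 or 3. The number was 8 without control replicate 3 and at most 14.

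Genes of the exocrine pancreas fell as well. Of 22 measured pancreas genes 12 fell, with log2 fold changes between -3.56 and -1.1, and none rose, with 20 lower when adjusted over the list alone. The pancreatic disulphide isomerase gene pdia2 went from 84.6 ± 10.9 to 27.8 ± 4.2 CPM (SD, n = 3 each, log2 fold change -1.61, SE 0.14, adjusted p = 0.00140), and the trypsin gene prss59.1 from 175 ± 35.7 to 26.4 ± 12.4 CPM (log2 fold change -2.74, SE 0.33, adjusted p = 0.00474), a value that reads shared with its copy prss59.2 could shift. The list had a median of -1.83 and was lower as a set (adjusted p = 5.71e-30), with adjusted p = 0.0530 with an estimated correlation. Control replicate 1 lay a median of 0.53 above the other controls over this list, and 11 genes were called without it, 5 without mutant replicate 2 and 4 without mutant replicate 3. Of 48 liver and intestine genes 7 rose and 7 fell, with 9 higher and 13 lower when adjusted over the list alone. DESeq2 called 10 higher and 12 lower. The 7 that rose included plasma proteins of the liver, such as the copper carrier ceruloplasmin cp (132 ± 14.6 to 241 ± 9.54 CPM, log2 fold change 0.87, SE 0.11, adjusted p = 0.00453) and the complement gene c3a.1 (276 ± 72.1 to 717 ± 9.85 CPM, log2 fold change 1.38, SE 0.17, adjusted p = 0.00544), one of a family of close copies. The 7 that fell, with log2 fold changes between -2.77 and -0.61, included the intestinal genes fabp2 and vil1. This list thus mixed rises and falls, and it did not differ in 1 direction as a set (median 0.02, and -0.07 with scaling by library size alone, mean -0.20, adjusted p = 0.646, direction up). The number of its genes that were lower was 0 without mutant replicate 1 and 1 without control replicate 3 or mutant replicate 3, and 2 without mutant replicate 2, and 3 of its genes were higher without mutant replicate 1 or 2.

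Of 40 cartilage and craniofacial genes none passed in edgeR, over all genes or adjusted over the list alone, nor in limma-voom, while DESeq2 called 2 higher and 2 lower, and 7 had an unadjusted p under 0.05. In edgeR 1 of these genes was higher without control replicate 1, and 2 were higher and 3 lower without control replicate 2. The collagen gene col1a1 (ENSDARG00000035809) stood at 2239 ± 160 CPM in controls and 2562 ± 112 CPM in mutants (SD, n = 3 each, log2 fold change 0.19, adjusted p = 0.418). A separate gene named col1a1a had a log2 fold change of 0.69 and did not pass either (adjusted p = 0.0692). The list had a median of -0.05 (adjusted p = 0.935). Of 46 skeletal muscle genes 3 fell and none rose in edgeR, with 4 higher and 3 lower when adjusted over the list alone. DESeq2 called 10 of them higher and 3 lower, and limma-voom 2 lower. Without control replicate 2, edgeR called 3 muscle genes higher and 1 lower. Those that fell included the myosin heavy chain gene myhb (161 ± 19.8 to 76.4 ± 20.1 CPM, log2 fold change -1.08, SE 0.19, adjusted p = 0.0232) and the myoglobin gene mb (log2 fold change -0.52, SE 0.10, adjusted p = 0.0304). The call for myhb ended without control replicate 3 or mutant replicate 3 (adjusted p = 0.0702 and 0.0826), and that for mb was kept only without control replicate 1, with adjusted p-values of up to 0.12 (without mutant replicate 1). The number of muscle genes that were lower was 0 without mutant replicate 3 and 1 without control replicate 2, control replicate 3, mutant replicate 1 or mutant replicate 2. The muscle list as a set was nevertheless higher, with a median of 0.28 and an adjusted p of 2.58e-05, a call lost with an adjusted p = 0.345 with an estimated correlation. In control replicate 1 its members lay a median of 0.31 below the other controls on the log2 scale. With an estimated correlation, the set calls of the MCM helicase, mitosis, p53, Stat1 and interferon, and caspase lists held. So did those of the neutrophil and macrophage, neural progenitor, and photoreceptor and lens lists, and all these adjusted p-values lay between 0.0353 and 0.0484. The MCM helicase list included mcm5 in this test, and without mcm5 it was not tested with an estimated correlation.

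**Figure D2:**
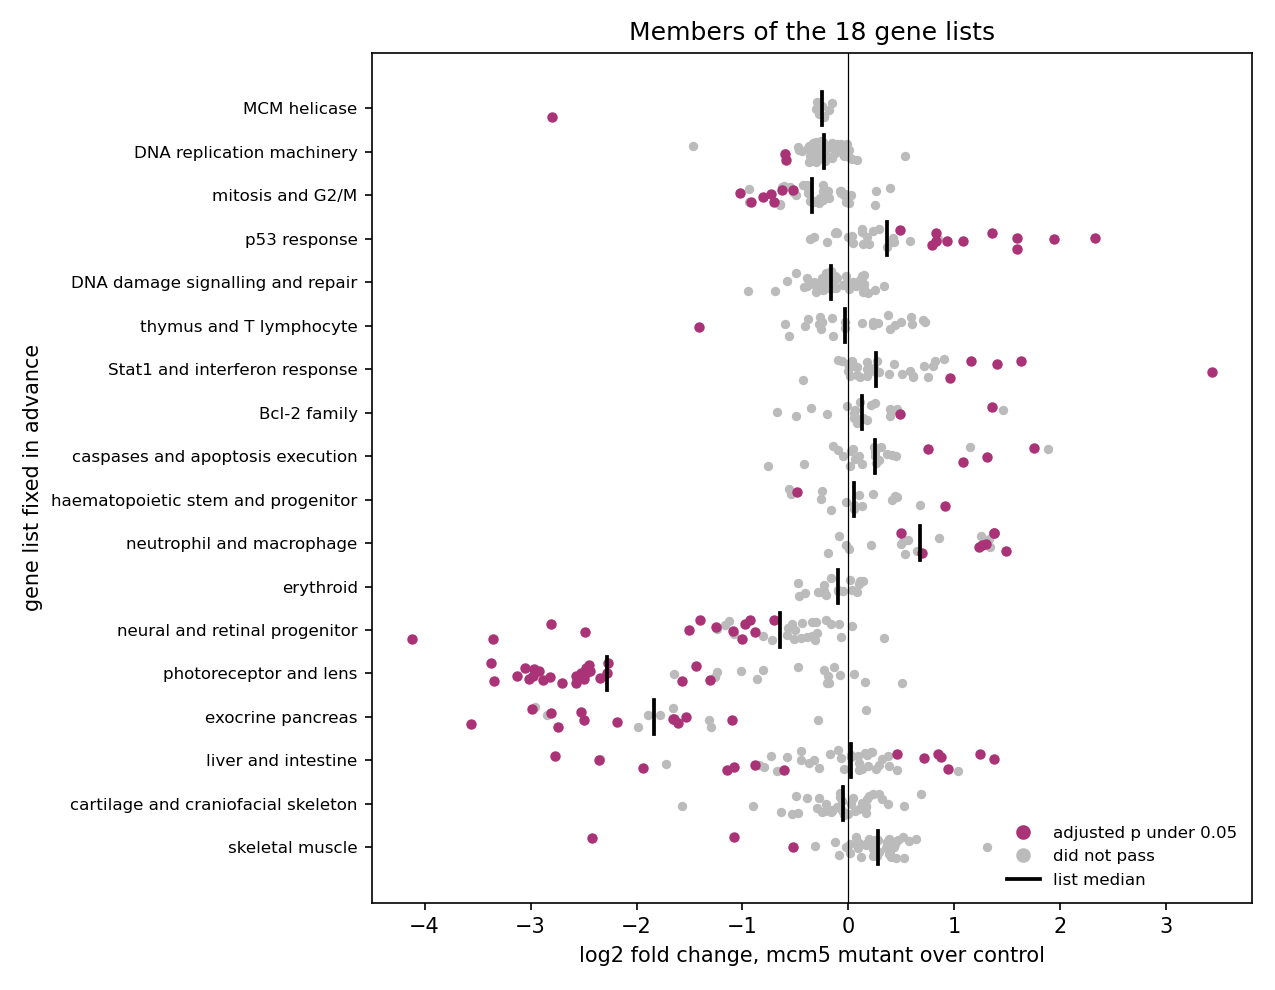
Log2 fold change (mcm5 mutant over control) of every tested member of the 18 gene lists, with 1 line of points per list, members past an adjusted p of 0.05 in purple, the others in grey and the list median as a black bar. The photoreceptor and lens list sits at a median of -2.28, the exocrine pancreas list at -1.83 and the neutrophil and macrophage list at 0.67.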

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

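Leaving out the features without an Ensembl gene and changing the members of lists were chosen after seeing the data. The fall of mcm5 kept its call under all 14 alternatives, with log2 fold changes between -2.90 and -2.71. The total of 910 genes became 915 with DESeq2 size factors, 809 with library size alone, 983 with no filter, 910 with the stricter filter, 798 with limma-voom, 1035 without the features without an Ensembl gene and 1423 with DESeq2, and none of the 910 that these fits tested changed sign. Higher genes numbered 589 with DESeq2 and 210 with library size alone, and library size alone shifted all genes by -0.11. In the simulation DESeq2 called 27 unchanged genes, against 8 with edgeR, and found 9 against 3 of 50 genes changed 1.5-fold. How much of the DESeq2 difference in the real data comes from either was not tested. With 1 sample left out, which leaves fewer samples, the total lay between 331 and 869, higher genes between 108 and 351, lower genes between 223 and 530, and genes changed at least 2-fold between 284 and 543.

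With an estimated correlation the calls of the DNA replication (adjusted p = 0.0791), Bcl-2 (0.368), exocrine pancreas (0.0530) and muscle (0.345) lists ended. The camera test of the DNA damage list passed with no filter (0.0335) and limma-voom (0.00924). The fry test asks whether the genes of a list move one way on balance, and not, as camera does, whether they differ from other genes. By fry the Bcl-2 and muscle lists did not pass (0.0849 for both) and the DNA damage list did (0.00519), which is an answer to that other question. The Bcl-2 list without its p53 members gave 0.144. With 1 sample left out, the adjusted p of the DNA damage list lay between 0.0380 and 0.146, that of the Bcl-2 list between 0.000590 and 0.0939, and that of the erythroid list between 0.0313 and 0.968. The causes were not tested. Replicate numbers are shared by the groups, but samples with the same number did not deviate together (correlations 0.026, -0.050 and 0.176 across genes), and not every sample correlated best with its own number. The fit with the replicate number as a block called 915 genes, 706 of them among the 910. Of the 38 named genes past the threshold, 35 kept their calls under this replicate block (all but slbp, hmga1a and bax, adjusted p = 0.0602, 0.111 and 0.0573) and 29 to 36 with 1 sample left out, and no list test changed its call under the block. At this depth, spread and number of samples, 3 of 50 simulated genes changed 1.5-fold were found, and depth was not varied alone.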

Other observations

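The 7 lists of this part and all tests of this part except the count of other splits were chosen after the results were seen. Some list members, such as c3a.1, vil1, cxcl18b and the photoreceptor genes, had already been seen to change. The p-values of these 7 lists therefore describe the lists and give no independent support. Genes of motile cilia were higher in the mutants. Of 80 measured members 11 rose and none fell, among them the ciliogenesis transcription factor gene foxj1 (ENSDARG00000101919, log2 fold change 1.4, SE 0.15, adjusted p = 0.00297) and the dynein gene dnah5l (log2 fold change 0.98, SE 0.15, adjusted p = 0.0126), and the list median was 0.77 (camera, adjusted p = 9.71e-21 over these 7 lists, adjusted p = 0.0324 with an estimated correlation). Of 37 AP-1 and NF-kB response genes 14 rose and none fell, such as fosl2 (log2 fold change 1.28, SE 0.12, adjusted p = 0.00170) and the inhibitor gene nfkbiaa (log2 fold change 1.59, SE 0.24, adjusted p = 0.0115), with a median of 0.82 (adjusted p = 1.88e-21, adjusted p = 0.0331 with an estimated correlation). Of 30 complement genes 12 rose and none fell in edgeR, while DESeq2 called 13 higher and 1 lower. Those that rose included c4b (log2 fold change 1.64, SE 0.16, adjusted p = 0.00201), and the list had a median of 0.63 (adjusted p = 4.63e-14, adjusted p = 0.0324 with an estimated correlation).

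Genes of synapses and of enterocytes were lower. Of 49 measured synapse genes 15 fell and none rose, such as syt5b (log2 fold change -2.19, SE 0.17, adjusted p = 0.00101). The median was -0.60 (adjusted p = 7.00e-22, lost with adjusted p = 0.135 with an estimated correlation), and 36 had an unadjusted p under 0.05. Others changed less, such as snap25 (ENSDARG00000020609, log2 fold change -0.23, adjusted p = 0.398) and syt1 (log2 fold change -0.37, adjusted p = 0.229). Whether this fall was separate from that of the photoreceptor genes was not tested. Of 44 enterocyte genes 11 fell in edgeR, with a median of -0.97, while DESeq2 called 26 lower and limma-voom 5 (adjusted p = 1.09e-14, lost with adjusted p = 0.135 with an estimated correlation), and 7 were lower without control replicate 1. The 1 enterocyte gene that was higher in edgeR, alpi.1 (log2 fold change 0.57, SE 0.12, adjusted p = 0.0416), did not pass in DESeq2 or without control replicate 1. The brush border gene vil1 stood at 337 CPM in control replicate 1, at 95.0 and 142 CPM in the other controls and at 37.6 ± 16.3 CPM in mutants (SD, n = 3). Taken apart, the 28 photoreceptor members had a median of -2.51 with 25 lower (adjusted p = 3.42e-111, adjusted p = 0.0208 with an estimated correlation), and the 13 lens members a median of -0.23 with none passing in edgeR or limma-voom, 2 lower in DESeq2 and 6 at an unadjusted p under 0.05 (adjusted p = 0.00382 as a set, lost with adjusted p = 0.327 with an estimated correlation). The feature Novel03802, which carries no Ensembl gene, fell from 109 ± 10.9 to 14.9 ± 2.27 CPM (log2 fold change -2.87, SE 0.14, adjusted p = 0.000308). Of 4198 tested features without an Ensembl gene, 35 were higher and 78 lower.

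The real split of the 6 samples gave 910 genes, and the highest of the other 9 splits gave 1, so 1 of the 10 splits gave as many genes. With 10 splits the share cannot fall under 0.1. A second question was whether variants that travel with the mcm5 mutation may account for the calls. Among the 50 genes on each side of mcm5 in the RefSeq order of the GRCz12tu assembly, 6 of 100 were called, against 3.86% of 13093 other placed genes (Fisher's exact test, two-sided, p = 0.288). All 6 lay on the same side of mcm5, which was seen in the calls and gives no test of its own. The 100 neighbours made up 1.17% of the calls that could be placed. With 506 calls among the other placed genes, 100 neighbours could never have made up most calls. So this share cannot decide whether linked variants lie behind most calls, and it says nothing of variants further away. For the 6 neighbours, such as copz2 (log2 fold change -2.32, adjusted p = 0.0110) and kpna2 (log2 fold change 0.83, adjusted p = 0.00259), linked variants stay open.

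The fall of photoreceptor and pancreas genes may in part reflect the library of control replicate 1, in which both lists were high. Without that sample the median log2 fold change of the 37 called members was -2.47, against -2.52 with all samples, and 36 stayed past the threshold. These members were called with that sample in the fit. Over all members tested in each fit, the photoreceptor and lens median went from -2.28 to -2.18 and the pancreas median from -1.83 to -1.57. These values argue against control replicate 1 as the whole source, while a part stays open, more so for the pancreas. Scaling between libraries would shift other tissues as well, but the 105 cartilage, erythroid and muscle members had a median of 0.087 and a lower quartile of -0.16, above the upper quartiles of all tested photoreceptor and lens members (-0.81) and pancreas members (-1.56). Slower development of the mutants stays open. The cartilage members had a median of -0.054 (quartiles -0.22 and 0.16), and a delay of some tissues cannot be told apart from a loss of their cells at 1 age.

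The rise of neutrophil and macrophage genes may likewise come from control replicate 1, where they were low. Without it the 8 called members kept a median of 1.17, against 1.28, and 6 stayed past the threshold. These members were called with that sample in the fit. Over all members tested in each fit the median went from 0.67 to 0.55, which argues against control replicate 1 as the whole source. A smaller share of eye and pancreas RNA would raise all other tissues alike, but the cartilage, erythroid and muscle members had an upper quartile of 0.29, below the lower quartile of 0.50 of the 22 neutrophil and macrophage members. Whether the mutants hold more neutrophils and macrophages or more transcript in each cannot be told apart. Whole-fish RNA gives neither a count of cells nor the cells a transcript came from. The rises of the 8 called members ran from 0.50 (lcp1) to 1.48 (mmp9), with SE of at most 0.29.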
